A study of Mus musculus with 18 samples.

How the data were processed

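Total RNA of 18 newborn mouse hearts was sequenced, 3 biological replicates of each sex and each Chd7 genotype (WT, T720A het, T720A hom). Per the labels' protocols, RNA was purified on columns, ribosomal RNA was depleted, and libraries were built with a stranded total RNA kit. The authors deposited raw counts of reads per gene in a table of the whole series, with 55487 mouse Ensembl gene IDs and a symbol for each, and 114 symbols are given to more than 1 gene. Per the submitters' processing notes, Trim Galore, STAR and featureCounts were used, and their versions and settings are not given in the sources used here. The same notes name the human build hg38, while the gene IDs are mouse IDs, of which 55141 are among the 55450 genes of the GENCODE M21 annotation of GRCm38. No coordinates are in the table, so those printed come from GENCODE M21 and GRCm38.

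All 37 genes of the mitochondrial genome and 1173 of 1507 snoRNA genes have 0 counts in every library, so these classes could not be studied. Whether counting used the strand is not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart, and levels of genes with near-identical copies, such as globin, heat shock and ribosomal protein genes, are uncertain. The replicates are separate hearts per the study's design text, which gives no litter, batch or date. The closest pair among all pairs of libraries differed by a chi-square of 8.82 per degree of freedom, so no library was counted as a repeat of another. Each column of the table matched the title of 1 sample.

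Library sizes were the column sums, 14.1 to 37.2 megareads, scaled with TMM factors of 0.948 to 1.19. Precision differs accordingly: 1 CPM stands for fewest counts in the hom females, and counts vary between hearts far beyond counting error, with a common dispersion of 0.134. Genes were kept with the filterByExpr function at its minimum count of 10 and minimum total of 15, which left 19769. The main test was the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with 1 mean for each of 6 groups in a fit of all 18 libraries, so that all groups share an estimate of the spread. There were 10 contrasts: hom against WT, het against WT and hom against het as means of the differences within each sex, hom and het against WT in males and in females, the male minus the female effect of each genotype, and WT males against WT females. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold. Errors of log2 changes are standard errors derived from the quasi-likelihood F statistic, CPM values are given with their SD, and log2 CPM used a prior count of 2.

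Genes named in the text follow a rule fixed before the data were examined. In hom against WT and het against WT over both sexes and in hom against WT in males and in females it took the 10 genes of smallest p in each direction that passed with a mean of at least 1 CPM and a symbol that is not a predicted name. In the other contrasts it took 5. Where no gene passed, it took the 3 of smallest p in each direction. Chd7, Xist, Ddx3y, Kdm5d, Uty and Eif2s3y were added, as were up to 4 members of smallest p in each list described. Library markers such as Col2a1, Hbb-bs, Fos, Rag1 and Cd8a were named after their values were seen, as were the libraries called doubted.

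Also fixed beforehand were 34 gene lists, of which 33 had 3 or more genes tested. They are the sarcomere, the cardiac stress and fetal program, calcium handling, ion channels and conduction, cardiac transcription factors, the nuclear encoded respiratory chain, mitochondrial genome mRNAs, fatty acid oxidation, glycolysis and hypoxia, the extracellular matrix, the cell cycle, p53 targets, the integrated stress and unfolded protein response, immediate early and heat shock genes, the interferon response, cytosolic ribosomal proteins, CHD and SWI/SNF remodelers, semaphorin signaling and neural crest, and the circadian clock. Markers of atrial and ventricular cardiomyocytes, cardiac fibroblasts, endothelium, smooth muscle and pericytes, epicardium, macrophages and immune cells, erythroid cells, Schwann cells and neurons, thymus and lymphoid tissue, lung epithelium, liver, skeletal muscle and brown fat, and sex-linked genes complete them. For each list the members past the threshold were counted over all genes and again with p-values adjusted over the list alone. The camera test of limma 3.58.1 was run on log2 CPM with a preset correlation of 0.01 between genes and, as an alternative, with the correlation estimated from the data, adjusted over the lists of a contrast. No list passed in any contrast with an estimated correlation. The level of a list in a library is the mean over its members of log2 CPM minus the gene's mean over 18 libraries.

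The tests were tried on simulated counts drawn from the real means, library sizes and dispersions, with 200 genes changed by known folds. Each gene was drawn independently around its mean over all libraries, so shared differences between libraries, such as thymus content, were absent. The recoveries therefore do not show how often such changes are found in the real libraries. Simulating hom against WT over both sexes with 19271 genes tested, edgeR recovered 20% of 50 genes changed 1.5-fold, 72% of those changed 2-fold, 94% at 4-fold and 96% at 8-fold, and called 6 unchanged genes. Simulating hom against WT in males with 19261 genes tested, it recovered 8%, 38%, 84% and 92%, and called 4 unchanged genes. In simulated counts of 19288 genes with the fatty acid oxidation list raised by 0.5 log2 units in hom against WT, camera gave that list an adjusted p of 8.04e-15 with the preset and 1.87e-04 with the estimated correlation, and called 1 of the other 32 lists. Members of a list were drawn independently there, unlike in the real libraries. This result therefore does not show what the test with an estimated correlation can find in the real lists.

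The settings varied by plan were RLE size factors, DESeq2 1.42.0, limma voom with sample quality weights, no filter on low counts, a filter of at least 1 CPM in at least 3 libraries, a test against a fold of 1.2 with glmTreat, only the groups of a contrast, up to 3 surrogate variables from sva 3.50.0, the replicate number as a block, and leaving out each library in turn. Chosen after seeing the data were fits without the 4 libraries whose thymus list level lay 5 or more log2 units above the median library, without the 4 with a cell cycle level of at most -0.3 and a fatty acid oxidation level of at least 0.5, without the 7 libraries that either rule takes, and with the thymus, lung and fatty acid oxidation levels as covariates. Other splits of the libraries were drawn, 30 for contrasts of 4 groups and all 10 for contrasts of 2. Correlations across libraries used 100000 permutations, and comparisons of few libraries used exact two-sided permutation tests. With 3 libraries against 3 the smallest p such a test can give is 0.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.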

Results

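Hearts of newborn C57BL/6 mice, taken on postnatal day 0, were profiled by sequencing of total RNA after removal of ribosomal RNA. The mice were wild type (WT), heterozygous (het) or homozygous (hom) for the T720A missense allele of Chd7, which encodes a chromatin remodeler of the CHD family. The series addresses a disease of heart muscle tied to this allele. Each genotype was represented by 3 male and 3 female biological replicates, which gives 6 groups and 18 libraries. The deposited table holds read counts for 55487 genes. Counted reads per library ranged from 14.1 to 37.2 megareads (M), with a median of 28.9 M. Depth was lowest in the hom females, at 14.1 to 29.9 M, and was 31.5 to 34.0 M in the WT males. Of all genes, 19769 had enough counts to be tested, and their common biological coefficient of variation between replicates of a group was 0.366.

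Chd7 mRNA was present in every library, at 34.4 to 81.3 CPM (counts per megaread) in WT, 57.7 to 88.1 CPM in het and 42.4 to 69.8 CPM in hom hearts. The mean was 57.8 ± 16.4 CPM in WT, 70.2 ± 12.8 in het and 57.5 ± 10.3 in hom (SD, n = 6 each). On library sizes without TMM scaling it was 57.1 ± 13.3, 67.8 ± 12.5 and 59.0 ± 7.62. The log2 change was -0.01 ± 0.18 SE in hom (edgeR adjusted p = 0.983) and 0.28 ± 0.18 SE in het (edgeR adjusted p = 0.976) relative to WT. A missense allele leaves the transcript in place, so this level checks neither the allele nor the genotype labels. Chd7 (ENSMUSG00000041235) lies on the plus strand of chromosome 4 at 8690406 to 8867659 in GRCm38. The codon of threonine 720, ACA, is at 8801415 to 8801417 in exon 4 of the 38 exons of the transcript ENSMUST00000039267, whose protein has 2986 residues.

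The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y and the X-inactivation transcript Xist separated the sexes as labelled. Mean CPM over the 9 male libraries was 103 for Ddx3y, 31.3 for Kdm5d, 24.4 for Uty and 89.5 for Eif2s3y. Xist was at 358 to 1085 CPM in female and at 0.217 to 48.9 CPM in male libraries, with the highest male value in het male replicate 1. In het female replicate 1 the 4 Y-linked genes reached 7.80% to 11.6% of their male means. The mean of the 4 percentages was 3.48 in hom female replicate 3, 3.16 in hom female replicate 2, 2.66 in WT female replicate 1 and 2.03 in het female replicate 2, and 0 to 0.430 in the other 4 female libraries.

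Several libraries stood apart from others of their own group. Summed transcripts of 15 thymus and lymphoid markers, genes of developing T cells and of thymic epithelium, were at 2694 CPM in WT female replicate 2, 3252 in hom male replicate 3, 4065 in hom female replicate 1 and 3921 in hom female replicate 2. The other 14 libraries held 6.11 to 328 CPM. Lung epithelial markers, among them surfactant genes, summed to 3560 CPM in WT female replicate 2 and 2703 in hom female replicate 1, against 313 to 668 CPM elsewhere. The list also holds Hopx, a member of the cardiac transcription factor list, so its sum is not lung content alone. The surfactant gene Sftpc was at 1732 and 1317 CPM in these libraries in this order. Its level was 146 CPM in WT female replicate 3, 129 in hom male replicate 3 and 78.2 in het female replicate 3. Elsewhere Sftpc was at 0.124 to 22.1 CPM. Genes of cell division were low and genes of fatty acid oxidation high in WT male replicates 1 and 2, het female replicate 1 and hom female replicate 2. In this order the mean cell cycle level was -1.54, -2.22, -1.02 and -0.37 log2 units from the average library and the fatty acid oxidation level 1.06, 1.31, 1.23 and 0.56. The cartilage collagen Col2a1 was at 733 CPM in hom male replicate 2 and 447 CPM in WT female replicate 2. The beta-globin gene Hbb-bs was at 6351 CPM in hom female replicate 3, and the immediate early gene Fos at 159 CPM in hom female replicate 1. The neuronal tubulin gene Tubb3 was at 70.3 and 33.8 CPM in het male replicates 1 and 2 and at 5.33 CPM in replicate 3, and summed Schwann and neuronal markers at 272, 209 and 124 CPM. Clock genes summed to 1395 CPM in hom female replicate 3, the highest of all libraries, with Nr1d1 at 97.2 CPM. In a principal component analysis the leading component carried 51.7% of the variance, with the T cell genes Rag1 and Cd8a at its upper end and the Y-linked genes and Ucp3 at its lower end.

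**Figure D1:**
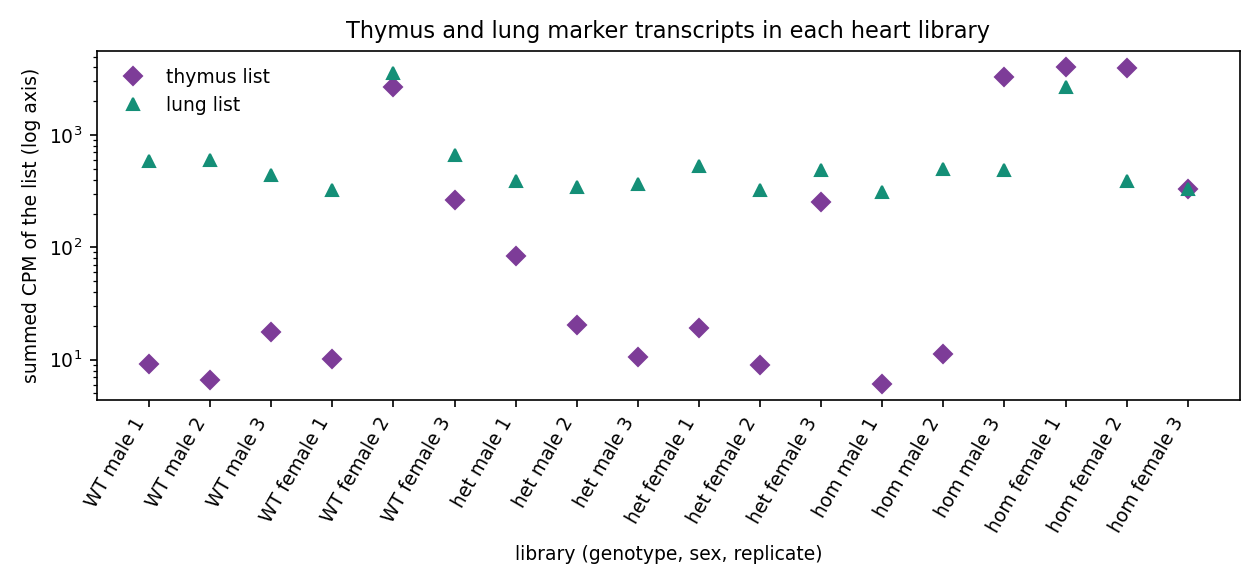
Summed CPM (log axis) of the thymus and lymphoid list and of the lung epithelial list in each of the 18 libraries. Thymus transcripts were between 2694 and 4065 CPM in 4 libraries and at most 328 CPM in the other 14, and lung transcripts were highest in WT female replicate 2 and hom female replicate 1. The lung list also holds Hopx, a member of the cardiac transcription factor list, so low sums are not lung content alone.

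The comparison of hom with WT hearts over both sexes asks what the loss of the reference residue on both alleles does to the heart transcriptome. Immediate early and heat shock genes, which many cells switch on soon after a stimulus or stress, were higher in hom hearts in 28 of 32 members, with a median log2 difference of 0.68. Fosb, an AP-1 subunit, differed by 3.45 ± 0.73 SE, the nuclear receptor Nr4a1 by 1.65 ± 0.37, the stress-induced factor Atf3 by 1.69 ± 0.41 and the zinc finger factor Egr3 by 1.47 ± 0.39. Fatty acid oxidation genes, which supply most of the energy of the adult heart, were lower in 34 of 34 members (median log2 difference -0.48). Among them were Pdk4, a kinase that restrains glucose oxidation (-1.43 ± 0.41), Angptl4, an inhibitor of lipoprotein lipase (-1.45 ± 0.53), the acyl-CoA thioesterase Acot2 (-1.0 ± 0.38) and Cpt1a, which moves fatty acids into mitochondria (-0.57 ± 0.23). Cell cycle genes were higher in 47 of 49 members (median 0.36), with the replication helicase genes Mcm4, Mcm5 and Mcm6 at 0.81 ± 0.32, 1.04 ± 0.46 and 0.75 ± 0.35 and E2f2 at 1.76 ± 0.65.

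No single gene passed the test in this comparison: edgeR called 0 of 19769 genes, with 2562 at an unadjusted p under 0.05 (1791 higher and 771 lower in hom), while DESeq2 called 40 and limma voom with sample quality weights 1763. The smallest edgeR adjusted p was 0.336. Genes of smallest p with higher levels in hom were Arid5a, which encodes an RNA-binding protein that stabilizes inflammatory transcripts, at 32.9 ± 6.89 against 19.9 ± 6.27 CPM (SD, n = 6), Cd72, an inhibitory receptor of B cells, at 2.49 ± 0.523 against 1.09 ± 0.405 CPM, and the zinc finger gene Zbtb2 at 29.1 ± 4.11 against 20.3 ± 3.80 CPM. Their log2 differences were 0.77 ± 0.14, 1.24 ± 0.25 and 0.53 ± 0.11 SE. Those of smallest p with lower levels were Ttc30b, a component of intraflagellar transport, at 11.7 ± 2.22 against 16.4 ± 1.39 CPM, the mitochondrial enzyme of phosphoenolpyruvate synthesis Pck2 at 30.4 ± 4.88 against 44.3 ± 8.19 CPM, and Ppm1k, the phosphatase that activates branched-chain amino acid breakdown, at 58.6 ± 9.35 against 83.3 ± 22.6 CPM. Their log2 differences were -0.50 ± 0.10, -0.53 ± 0.12 and -0.46 ± 0.11 SE. Without the 4 libraries rich in thymus transcripts edgeR called 3 genes. It called 242 without these and the 4 of low cell cycle level, 7 libraries in all, which leaves 1 WT male and 1 hom female library.

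**Figure D2:**
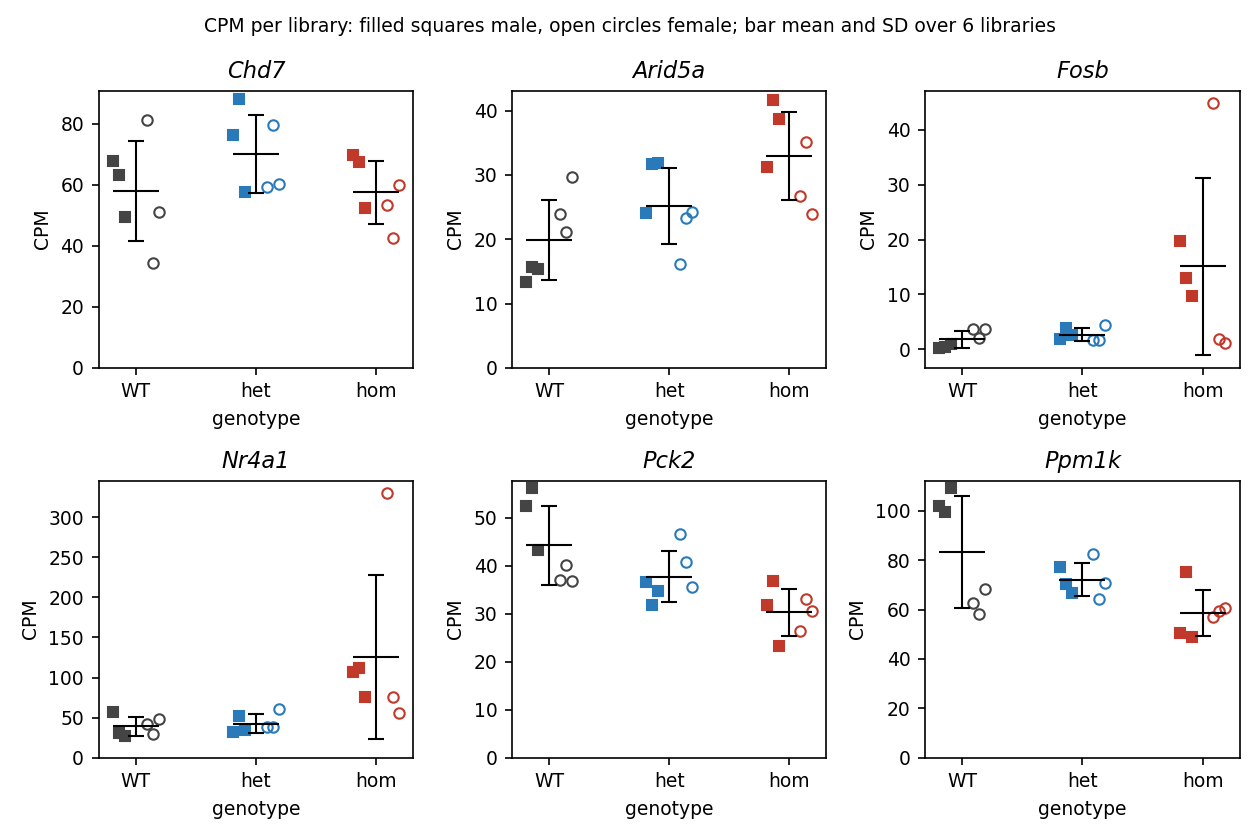
CPM per library of Chd7, Arid5a, Fosb, Nr4a1, Pck2 and Ppm1k by genotype, with filled squares for males, open circles for females, and bars for the mean and SD over 6 libraries. Arid5a was at 19.9 CPM on average in WT and 32.9 in hom hearts, and the hom mean of Fosb, 15.1 CPM, included 44.8 CPM in hom female replicate 1.

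Counted over the fixed lists, 13 immediate early and heat shock members rose and 1 fell in hom hearts when adjusted over the list alone, against 0 over all genes tested. The limma camera adjusted p of this list was 7.41e-08 with the preset correlation, and adjusted p = 0.740 with an estimated correlation. Fosb was at 19.7, 13.1 and 9.82 CPM in the hom males and at 44.8, 1.93 and 1.19 CPM in the hom females, against 0.334 to 3.77 CPM in WT. Leaving out the 4 thymus-rich libraries, of which hom female replicate 1 had the highest Fos, brought the list to 5 members that rose and 1 that fell, adjusted over the list alone, with a median of 0.18. Fatty acid oxidation (camera adjusted p = 4.91e-11) and the cell cycle (1.78e-09) each had 0 members past the threshold by either count, and both calls were lost with an estimated correlation (adjusted p = 0.740 for each). Of the 4 libraries in which these lists stood apart, 2 were WT males and 1 was a hom female. Outside the 7 doubted libraries the fatty acid oxidation level was -0.45 to -0.25 in hom and -0.11 to 0.27 in WT. That difference kept its direction, though with only 1 hom female and 1 WT male left. Without the 7 doubted libraries the cell cycle median turned to -0.32, with 29 members that fell in hom adjusted over the list alone. Hom females were then represented by replicate 3 alone, at a cell cycle level of -0.26 against 0.36 and 0.37 in WT females, while the male levels were 0.43 and 0.38 in hom and 0.40 in WT. Thymus markers were higher in hom in 15 of 15 members (median 4.26, camera adjusted p = 5.96e-06, and adjusted p = 0.740 with an estimated correlation). Of these, 15 rose adjusted over the list alone against 0 over all genes. Of the skeletal muscle markers 12 of 15 were higher (median 1.24, camera adjusted p = 6.23e-05), 6 rose adjusted over the list alone against 0 over all genes, and with an estimated correlation the adjusted p was 0.553. These included Myog (1.52 ± 0.38 SE), Tnnt3 (1.24 ± 0.35), Myh4 (2.99 ± 0.88) and Mylpf (1.49 ± 0.45), all low in the heart. Myh4 was at 0.596 to 1.71 CPM in the 4 thymus-rich libraries and at most 0.299 CPM in the others.

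Several heart muscle lists, though not atrial markers, were on the lower side in hom hearts. Nuclear genes of the respiratory chain were lower in 54 of 54 members (median -0.23, camera adjusted p = 1.33e-06), and sarcomere genes in 26 of 32 (median -0.23, 0.0151). So were ion channel and conduction genes in 26 of 31 (median -0.21, 0.00382), ventricular markers in 11 of 12 (median -0.23, 0.0338) and endothelial markers in 19 of 21 (median -0.13, 0.00828). Irx3, a factor of the conduction system, differed by -0.68 ± 0.20 SE and Hey2, a factor of ventricular identity, by -0.54 ± 0.18. Interferon response genes were higher in 31 of 33 members (median 0.34, camera adjusted p = 2.98e-05), cytosolic ribosomal proteins in 63 of 75 (median 0.09, 1.15e-04), remodelers of the CHD and SWI/SNF families in 18 of 26 (median 0.18, 0.0167) and macrophage and immune markers in 15 of 21 (median 0.32, 0.0381). All 9 calls were lost with an estimated correlation (adjusted p = 0.740 for each), and none of these lists had a member past the threshold by either count. Thymus transcripts were high in 3 of the 6 hom and 1 of the 6 WT libraries. Sarcomere levels in those libraries were -1.07 to -0.45, endothelial levels -0.47 to -0.17 and respiratory chain levels -0.99 to -0.26. Among the other libraries the sarcomere level was 0.14 to 0.31 in hom and 0.07 to 0.35 in WT. The endothelial level there was 0.11 to 0.19 in hom and -0.004 to 0.21 in WT. Respiratory chain levels were -0.01 to 0.26 and 0.09 to 0.31. The lower sarcomere and endothelial levels in hom thus rested on the thymus-rich libraries. So did the higher macrophage and immune levels, at 0.98 to 1.43 there. In the other libraries these were -0.71 to -0.04 in hom and -0.67 to 0.05 in WT. Interferon levels were 0.25 to 0.73 in the thymus-rich libraries and -1.07 and -1.20 in WT male replicates 1 and 2. Elsewhere they were -0.37 to 0.17 in hom and -0.16 to 0.16 in WT. The interferon difference thus rested on the thymus-rich libraries and those WT males.

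The other fixed lists did not pass camera between hom and WT hearts. Cardiac transcription factors (median log2 difference -0.13, camera adjusted p = 0.0539), calcium handling (-0.11, 0.108), cardiac fibroblast markers (-0.06, 0.279), smooth muscle and pericyte markers (-0.04, 0.367) and liver markers (-0.20, 0.553) lay on the lower side. The cardiac stress and fetal program (0.16, 0.107), glycolysis and hypoxia (0.06, 0.332), atrial markers (0.14, 0.464), p53 targets (0.11, 0.524), the integrated stress and unfolded protein response (0.09, 0.260), Schwann and neuronal markers (0.13, 0.676), lung epithelial markers (2.15, 0.315), erythroid markers (0.17, 0.980), epicardial markers (0.00, 0.832) and sex-linked genes (0.11, 0.585) lay on the higher side or at 0. In 4 lists the median, the mean and the direction of the test differed in sign: the extracellular matrix (median 0.04, mean 0.08, tested lower, adjusted p = 0.896), semaphorin signaling and neural crest (-0.03, 0.01, lower, 0.315), the circadian clock (-0.05, 0.01, lower, 0.497) and brown fat markers (-0.15, 1.02, lower, 0.524). Adjusted over the list alone, 1 stress program member (Atf3) and 1 p53 target rose, 1 p53 target and 1 stress response member (Pck2) fell, and 1 brown fat marker rose and 1 fell, against 0 over all genes. All 13 mRNAs of the mitochondrial genome had 0 counts in every library and were not testable.

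**Figure D3:**
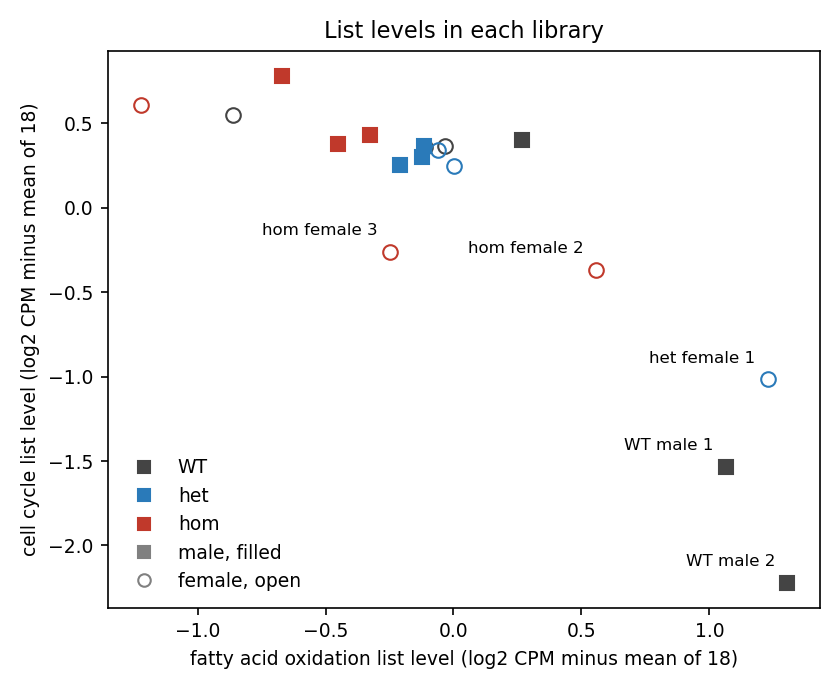
Mean level of the cell cycle list (y axis) against that of the fatty acid oxidation list (x axis) in each library, both as log2 CPM minus the mean of the 18 libraries. WT male replicates 1 and 2, het female replicate 1 and hom female replicate 2 combined cell cycle levels of -0.37 or below with fatty acid oxidation levels of 0.56 or above.

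Het hearts were compared with WT hearts over both sexes to ask what 1 copy of the allele does. Interferon-stimulated genes, the antiviral program of most cells, were higher in het in 28 of 33 members (median log2 difference 0.37), among them the guanylate-binding protein gene Gbp3 (0.56 ± 0.18 SE) and Ifit3b (1.05 ± 0.34), Ifi44 (1.24 ± 0.41) and Ifit3 (0.94 ± 0.33). Respiratory chain genes were higher in 54 of 54 members (median 0.14) and cell cycle genes in 47 of 49 (median 0.27), with cyclin D1, Ccnd1, at 0.41 ± 0.19. Liver markers, such as the apolipoprotein genes Apoa1 (-1.57 ± 0.44) and Apob (-4.01 ± 1.15), were lower in 8 of 9, with Apoa1 at a mean of 0.511 CPM. Genes of smallest p were, on the higher side, the glutamate receptor gene Grik3 at 5.51 ± 2.27 against 3.37 ± 0.598 CPM (SD, n = 6), Klrg2 at 1.54 ± 0.344 against 0.820 ± 0.299 CPM, with a highest WT value of 1.39 CPM, and the glycosyltransferase gene Mgat5b at 3.20 ± 1.41 against 1.79 ± 0.411 CPM. Their log2 differences were 0.66 ± 0.17, 0.94 ± 0.24 and 0.79 ± 0.21 SE. On the lower side they were the inositol kinase gene Itpka (-0.74 ± 0.20), xanthine dehydrogenase, Xdh (-1.62 ± 0.52), and the matrix proteoglycan gene Spock2 (-0.93 ± 0.30), with the highest het values of both in het female replicate 1 (37.8 and 65.9 CPM).

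None of these genes passed the test: edgeR called 0 of 19769 genes in het against WT hearts (smallest adjusted p 0.976), with 478 at an unadjusted p under 0.05, DESeq2 called 0 and limma voom with sample quality weights 1205. The limma camera adjusted p was 1.47e-10 for the interferon response, 9.97e-07 for the respiratory chain, 4.60e-09 for the cell cycle, 4.77e-06 for glycolysis and hypoxia (27 of 32 higher), 3.18e-04 for the extracellular matrix (47 of 54 higher), 7.24e-04 for the sarcomere (28 of 32 higher) and 0.00170 for the stress and fetal program (15 of 17 higher). Liver markers had 5.50e-04, and erythroid markers, lower in 13 of 13, had 0.00823. With an estimated correlation the adjusted p was 0.361 for liver markers and 0.859 for the 8 others. When adjusted over the list alone, 2 liver markers fell and no member of the others changed, and 0 did over all genes. The het groups held none of the 4 thymus-rich libraries, and WT held 2 of the 4 libraries of low cell cycle level against 1 in het. The respiratory chain level was -0.88 in the thymus-rich WT female replicate 2. It was 0.09 to 0.31 in the other WT and 0.11 to 0.29 in the het libraries. Sarcomere levels were -1.07, 0.07 to 0.35 and 0.13 to 0.27 in that order. Both differences thus rested largely on WT female replicate 2.

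Hom and het hearts, which share the allele and differ in its dose, were compared directly. Respiratory chain genes were lower in hom in 54 of 54 members (median log2 difference -0.37), with the complex III subunit gene Uqcrb at -0.43 ± 0.18 SE, and sarcomere genes were lower in 29 of 32 (median -0.41). Immediate early and heat shock genes were higher in hom in 29 of 32 (median 0.55), with Nr4a1 at 1.53 ± 0.37, the antiproliferative gene Btg2 at 1.33 ± 0.37, Fosb at 2.48 ± 0.69 and the phosphatase gene Dusp2 at 1.41 ± 0.43. Macrophage and immune markers were higher in 18 of 21 (median 0.46), led by the antigen presentation gene Cd74 (4.42 ± 1.22) and the leukocyte phosphatase Ptprc (4.10 ± 1.15). Thymus markers were higher in 15 of 15 (median 4.96), with Dntt, the polymerase of antigen receptor joining, at 5.29 ± 1.59. Single genes of smallest p were Fbrs (0.37 ± 0.07 SE), the tyrosine kinase gene Tnk2 (0.80 ± 0.17, and at 63.1 CPM in WT female replicate 2) and the mitochondrial iron importer Slc25a37 (0.71 ± 0.16) on the higher side. Usp43, a ubiquitin-specific protease (-1.18 ± 0.20), Zfp366 (-0.70 ± 0.16) and the endothelial exchange factor Arhgef15 (-0.58 ± 0.13) were on the lower side.

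In this comparison edgeR called 0 of 19769 genes (smallest adjusted p 0.126) with 3807 at an unadjusted p under 0.05, while DESeq2 called 1100 and limma voom with sample quality weights 2490. Leaving out hom female replicate 3, the library of most erythroid transcripts, gave 983 edgeR calls. The only hom females were then replicates 1 and 2, both rich in thymus transcripts, while the het groups held no thymus-rich library. Those calls may therefore reflect thymus content rather than genotype. In the lists, 15 immediate early and heat shock members, 10 macrophage and immune markers, 15 thymus markers, 6 skeletal muscle markers and 3 remodelers rose and 1 macrophage marker fell adjusted over the list alone, against 0 over all genes. The camera adjusted p was 1.38e-05 for immediate early and heat shock genes, 1.04e-13 for the respiratory chain, 7.65e-06 for the sarcomere, 0.00121 for macrophage and immune markers, 2.92e-06 for thymus markers and 0.0379 for both skeletal muscle markers and remodelers. With an estimated correlation each of these 7 had adjusted p = 0.609. Sarcomere levels were -0.91 to -0.45 in the thymus-rich hom libraries, 0.14 to 0.31 in the other hom and 0.13 to 0.27 in the het libraries. Respiratory chain levels were -0.99 to -0.26, -0.01 to 0.26 and 0.11 to 0.29 in that order. The lower sarcomere levels in hom thus rested on the thymus-rich libraries, as did most of the respiratory chain difference. Without the 4 thymus-rich libraries, 3 of which were hom, the macrophage median was 0.04 with 0 members past the threshold adjusted over the list alone, and the thymus median turned to -0.21. The immediate early and heat shock median was then 0.07 with 2 members that rose adjusted over the list alone.

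Among males, fatty acid oxidation transcripts lay lower and cell cycle transcripts higher in hom than in WT hearts. All 34 fatty acid oxidation genes were lower (median log2 difference -1.05), with the thioesterase gene Acot1 at -2.93 ± 0.72 SE, Pdk4 at -2.37 ± 0.59 (106 ± 33.7 against 546 ± 101 CPM; SD, n = 3), Cpt1a at -1.3 ± 0.33 and Angptl4 at -3.05 ± 0.80. All 49 cell cycle genes were higher (median 1.18), among them Mcm4 (1.58 ± 0.46), the thymidylate synthase gene Tyms (1.69 ± 0.52), Mcm6 (1.62 ± 0.50) and Mcm3 (1.85 ± 0.60). Genes of the integrated stress and unfolded protein response were higher in 24 of 30, with Atf4, the transcription factor of amino acid stress, at 0.98 ± 0.22 (222 ± 44.0 against 113 ± 5.54 CPM) and the endoplasmic reticulum gene Sdf2l1 at 1.24 ± 0.40. Pck2 at -0.72 ± 0.16 and the degradation gene Herpud1 at -1.15 ± 0.31 were lower. Immediate early and heat shock genes were higher in 26 of 32, with Atf3 at 2.57 ± 0.60, Fosb at 4.55 ± 1.09 (14.2 ± 5.06 against 0.598 ± 0.328 CPM), Nr4a3 at 2.74 ± 0.68 and Jund at 0.57 ± 0.16.

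Adjusted over the list alone, 21 fatty acid oxidation genes and 3 stress response genes fell and 10 stress response and 7 immediate early and heat shock genes rose, with 0 cell cycle genes past the threshold, against 0 over all genes for each list. The limma camera adjusted p was 4.41e-15 for fatty acid oxidation, 6.14e-21 for the cell cycle, 9.42e-04 for the stress response and 6.84e-05 for immediate early and heat shock genes. With an estimated correlation the adjusted p was 0.789 for immediate early and heat shock genes and 0.672 for the other three. Hom male replicate 3 was rich in thymus transcripts, and WT male replicates 1 and 2 were the libraries of lowest cell cycle level. Without the 4 low cell cycle libraries the cell cycle median was 0.06, 4 fatty acid oxidation genes fell adjusted over the list alone (median -0.45) and 0 stress response genes passed. WT males were then a single library. Immediate early and heat shock genes had a median of 0.69 without all 7 doubted libraries, and 16 of them rose adjusted over the list alone.

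Single genes of smallest p in hom against WT males were Arid5a at 37.2 ± 5.39 against 14.8 ± 1.23 CPM, the signal transducer of bone morphogenetic proteins Smad1 at 45.7 ± 3.37 against 28.2 ± 1.36 CPM and the amino acid transporter chain Slc3a2 at 83.6 ± 9.36 against 48.2 ± 2.44 CPM, each with its SD over 3 libraries. Their log2 differences were 1.34 ± 0.20, 0.70 ± 0.12 and 0.80 ± 0.14 SE. On the lower side were Ppm1k at 58.1 ± 14.7 against 104 ± 5.04 CPM (-0.83 ± 0.15), the bile acid family transporter Slc10a6 (-1.99 ± 0.39) and Cyyr1 (-0.93 ± 0.19). For Arid5a the edgeR adjusted p was 0.14, the smallest of 19769 genes. So edgeR called 0, with 4459 at an unadjusted p under 0.05, while DESeq2 called 1430 and limma voom with sample quality weights 4900. Leaving out WT male replicate 3 gave 1331 edgeR calls, and leaving out hom male replicate 2 gave 1. Without WT male replicate 3, the only WT males are replicates 1 and 2, the libraries of lowest cell cycle level.

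Among females, clock genes and chromatin remodelers lay higher and the extracellular matrix lower in hom than in WT hearts, with no member of these lists past the threshold. Circadian clock genes were higher in 18 of 19 members (median log2 difference 0.66), among them the repressors Nfil3 (0.68 ± 0.24 SE), Ciart (1.79 ± 0.65), Bhlhe41 (0.72 ± 0.28) and Bhlhe40 (0.69 ± 0.27). The clock level was 0.72 in hom female replicate 3 and -0.08 and 0.19 in replicates 1 and 2, against -0.09, -0.22 and -0.29 in WT females. Remodelers of the CHD and SWI/SNF families were higher in 19 of 26 (median 0.24), with the SWI/SNF subunit genes Arid2 (0.52 ± 0.17), Arid1a (0.55 ± 0.19) and Arid1b (0.42 ± 0.15) and the NuRD helicase gene Chd4 (0.50 ± 0.17). Matrix genes were lower in 50 of 54 (median -0.37), with the fibrillar collagens Col5a3 (-0.42 ± 0.15) and Col11a1 (-1.60 ± 0.62), the collagen chaperone Serpinh1 (-0.80 ± 0.38) and decorin, Dcn (-0.49 ± 0.23). Immediate early and heat shock genes were higher in 26 of 32 (median 0.54), with Nr4a1 at 1.94 ± 0.53, the chaperones Hspa1b and Hspa1a at 2.27 ± 0.75 and 2.21 ± 0.76 and Btg2 at 1.51 ± 0.52.

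The camera adjusted p in females was 2.41e-04 for the clock, 5.76e-04 for remodelers, 2.06e-06 for the matrix and 0.00736 for immediate early and heat shock genes. With an estimated correlation the adjusted p was 0.802 for remodelers and 0.939 for the other three, and no member passed the threshold adjusted over the list alone or over all genes. Of the 6 female libraries compared, hom replicates 1 and 2 and WT replicate 2 were rich in thymus transcripts. Without them the immediate early and heat shock median turned to -0.30 and the matrix median was -0.03, while the clock median was 0.86 with 7 members that rose adjusted over the list alone. Hom females were then represented by replicate 3 alone. Genes of smallest p were Fbrs at 108 ± 8.93 against 75.3 ± 8.37 CPM (SD, n = 3), the PHD finger gene Phf12 (0.53 ± 0.11 SE) and the microRNA exporter Xpo5 (0.51 ± 0.11) on the higher side. The dynein light chain gene Tctex1d2 (-0.91 ± 0.16), Ttc30b (-0.72 ± 0.15) and Rsu1 (-0.55 ± 0.12), which takes part in integrin adhesion, were on the lower side. Of 19769 genes edgeR called 0 (smallest adjusted p 0.609), with 1592 at an unadjusted p under 0.05, DESeq2 called 23 and limma voom with sample quality weights 4691. Without the 4 thymus-rich libraries edgeR called 544.

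Het males were compared with WT males. Interferon response genes were higher in het males in 32 of 33 members (median log2 difference 0.83), with Ifit3b at 1.85 ± 0.49 SE, the signal transducer Stat2 at 0.88 ± 0.24, Gbp3 at 0.93 ± 0.26 and Ifit3 at 1.68 ± 0.47 (8.82 ± 1.61 against 2.74 ± 1.38 CPM; SD, n = 3). Fatty acid oxidation genes were lower in 34 of 34 (median -0.78), among them the uncoupling protein gene Ucp3 (-5.29 ± 1.61). Cell cycle genes were higher in 49 of 49 (median 0.95), with Ccnd1 at 0.93 ± 0.27, Mcm4 at 1.09 ± 0.45, Cks1b at 0.94 ± 0.40 and Mcm3 at 1.38 ± 0.59. Genes of smallest p were Mgat5b (1.49 ± 0.29), the growth cone protein gene Basp1 (1.71 ± 0.34) and Arid5a (0.98 ± 0.20, 29.2 ± 4.43 against 14.8 ± 1.23 CPM) on the higher side. Tob2 (-1.04 ± 0.22), an antiproliferative gene, the channel gene Cngb3 (-3.46 ± 0.79) and the nuclear receptor gene Nr2c1 (-0.66 ± 0.16) were on the lower side. Basp1 was at 82.6 and 64.2 CPM in het male replicates 1 and 2, the libraries of high Tubb3, and at 31.8 CPM in replicate 3.

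Adjusted over the list alone, 16 interferon response genes rose, 4 fatty acid oxidation genes fell and 0 cell cycle genes passed in het males, against 0 over all genes. The camera adjusted p was 1.53e-13, 2.39e-11 and 6.34e-21 for these lists, and with an estimated correlation adjusted p = 0.749 for each. Without the 4 low cell cycle libraries, which leaves WT male replicate 3 as the only WT male, the fatty acid oxidation median was -0.22 with 1 member that fell adjusted over the list alone. The interferon median was then 0.40 with 0 members past the threshold, and the cell cycle median turned to -0.13. For het against WT males edgeR called 0 of 19769 genes (smallest adjusted p 0.236), with 2575 at an unadjusted p under 0.05, while DESeq2 called 328 and limma voom with sample quality weights 7245. Leaving out WT male replicate 3 gave 632 edgeR calls and leaving out het male replicate 3 gave 19.

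Among females, fatty acid oxidation and sarcomere transcripts lay higher and lung markers lower in het than in WT hearts. Fatty acid oxidation genes were higher in 34 of 34 members (median log2 difference 0.61), with Ucp3 at 4.44 ± 1.54 SE, Pdk4 at 1.43 ± 0.57 and the carnitine transporter Slc22a5 at 0.42 ± 0.20. Sarcomere genes were higher in 29 of 32 (median 0.37), with titin-cap, Tcap, at 0.77 ± 0.39 and the M-band protein gene Myom2 at 0.81 ± 0.54. Lung markers were lower in 12 of 13 (median -4.39), with Napsa, Cbr2, Epcam and Ager at -4.37 ± 1.60, -4.75 ± 1.87, -4.30 ± 1.86 and -3.57 ± 1.60. Het female replicate 1 had the highest fatty acid oxidation level of these libraries and WT female replicate 2 the highest lung level. Without the 7 doubted libraries the medians of fatty acid oxidation and the sarcomere turned to -0.05 and -0.02, and that of the lung list was -0.99.

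Camera gave the fatty acid oxidation list an adjusted p of 9.72e-14, the sarcomere 9.35e-09 and lung markers 2.38e-04 in het females, and with an estimated correlation adjusted p = 0.526 for each. No member passed the threshold adjusted over the list alone or over all genes. Genes of smallest p were the RNA polymerase I subunit gene Polr1b (0.43 ± 0.12 SE), Zbtb43 (0.38 ± 0.12) and the transmembrane glycoprotein gene Gpnmb (1.73 ± 0.54) on the higher side. The tight junction gene Cldn7 (-3.85 ± 1.05), the fibroblast growth factor carrier Fgfbp1 (-2.55 ± 0.73) and Mob3b (-1.37 ± 0.39) were on the lower side. The edgeR test called 0 of 19769 genes (smallest adjusted p 0.923), with 813 at an unadjusted p under 0.05, and both DESeq2 and limma voom with sample quality weights also called 0.

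The difference between the sexes in the effect of the hom genotype was tested as an interaction, the change in males minus that in females. Stress and unfolded protein response genes had a more positive change in males in 24 of 30 members (median 1.0), among them Atf4 (1.18 ± 0.31 SE), the chaperones Calr (1.34 ± 0.36) and Pdia6 (1.3 ± 0.35) and the proline synthesis gene Aldh18a1 (1.55 ± 0.43). Clock genes had a more negative change in males in 19 of 19 (median -1.11), including the output factors Hlf (-2.53 ± 0.61), Tef (-1.66 ± 0.50) and Dbp (-1.48 ± 0.46) and the repressor Bhlhe40 (-1.32 ± 0.39). Clock levels were 0.63 and 0.41 in WT male replicates 1 and 2 and 0.72 in hom female replicate 3, against -0.13 in WT male replicate 3, and all 3 high libraries enter this contrast with negative weight. Matrix genes had a more positive change in males in 51 of 54 (median 0.90), with Col5a3 at 0.80 ± 0.21, Col11a1 at 3.12 ± 0.88, Emilin1 at 1.18 ± 0.38 and Serpinh1 at 1.68 ± 0.54. Col11a1 was highest, at 174 and 86.1 CPM, in hom male replicate 2 and WT female replicate 2, the libraries of highest Col2a1, and both enter this contrast with positive weight. Single genes of smallest p were Tctex1d2 (1.15 ± 0.23), Mall (1.84 ± 0.37) and Smad1 (0.80 ± 0.16) in the positive direction. Those in the negative direction were Dido1 (-1.08 ± 0.19), Tob2 (-1.71 ± 0.31) and the DNA demethylase gene Tet3 (-1.36 ± 0.25).

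Adjusted over the list alone, 14 stress response genes passed with a positive and 3 with a negative difference in the hom interaction, and 8 clock genes with a negative one, with 0 matrix genes past the threshold, against 0 over all genes. The camera adjusted p was 3.54e-04, 1.56e-07 and 2.39e-08 for these lists, and with an estimated correlation adjusted p = 0.742 for each. Over all genes edgeR called 0 of 19769 (smallest adjusted p 0.154), with 3696 at an unadjusted p under 0.05, while DESeq2 called 737 and limma voom with sample quality weights 6182. Leaving out WT male replicate 3 gave 1259 edgeR calls, leaving out hom female replicate 1 gave 3, leaving out WT female replicate 2 gave 1 and leaving out each other library of the 4 groups gave 0. In the fit with 1259 calls, WT male replicates 1 and 2, both of low cell cycle level, were the only WT males. Without the 4 low cell cycle libraries edgeR called 0, with 663 at an unadjusted p under 0.05, and the clock median was -0.60 with 0 members past the threshold adjusted over the list alone. Without the 4 thymus-rich libraries the hom females were replicate 3 alone, the library of highest clock level. Calls from that fit may therefore reflect that single heart.

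The same interaction was tested for the het genotype. All 34 fatty acid oxidation genes had a more negative change in males (median -1.47), among them Ucp3 (-9.73 ± 2.23 SE), Acot1 (-3.64 ± 0.98) and Slc22a5 (-1.02 ± 0.29). All 33 interferon response genes had a more positive change in males (median 1.01), with Isg15 at 1.94 ± 0.68, Ifit1 at 2.04 ± 0.72, Stat2 at 0.84 ± 0.33 and Irf7 at 1.28 ± 0.51. Genes of smallest p were the phosphatase subunit gene Ppp2r2b (7.11 ± 1.41), Basp1 (2.29 ± 0.48) and the adhesion gene Cadm3 (3.63 ± 0.78) in the positive direction. All 3 were highest in het male replicates 1 and 2, the libraries of high Tubb3, and the Schwann and neuronal list had a median of 1.32 in this contrast (camera adjusted p = 0.00139, and adjusted p = 0.679 with an estimated correlation). In the negative direction they were Tob2 (-1.54 ± 0.31), the cytokine gene Il15 (-1.61 ± 0.33) and Zbtb43 (-0.74 ± 0.16).

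Adjusted over the list alone, 22 fatty acid oxidation genes passed with a negative difference in the het interaction and 0 interferon genes passed, against 0 over all genes. Camera adjusted p was 1.14e-16 and 1.05e-09, and with an estimated correlation adjusted p = 0.679 for both. WT male replicates 1 and 2 and het female replicate 1, the libraries of highest fatty acid oxidation level, enter this contrast with the same negative weight. Without the 4 low cell cycle libraries, with 1 WT male left, the median was -0.43 with 1 member past the threshold adjusted over the list alone. Without the 7 doubted libraries the interferon median turned to -0.10. In all, edgeR called 0 of 19769 genes (smallest adjusted p 0.252), with 2792 at an unadjusted p under 0.05, DESeq2 called 280 and limma voom with sample quality weights 3435. Leaving out WT male replicate 3 gave 359 edgeR calls, with WT male replicates 1 and 2, both of low cell cycle level, as the only WT males.

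WT males and WT females were compared as the background of the sex-specific contrasts. Uty, the Y-linked relative of the histone demethylase gene Kdm6a, on chromosome Y at 1096861 to 1245759 (GRCm38), was the 1 gene that passed. It was at 35.0 ± 3.49 CPM in males and 0.251 ± 0.263 CPM in females (SD, n = 3), with a log2 change of 7.14 ± 0.92 SE (edgeR adjusted p = 0.0281). Kdm5d, Eif2s3y and Ddx3y had log2 differences of 6.89 ± 1.23, 6.90 ± 1.17 and 6.41 ± 1.27, and Xist of -6.13 ± 1.51, each with an edgeR adjusted p of 0.205. Fatty acid oxidation genes were higher in WT males in 34 of 34 members (median 1.04), with Acot1 at 2.31 ± 0.70, Acot2 at 1.76 ± 0.54, Cpt1a at 1.04 ± 0.32 and Eci2 at 1.08 ± 0.36. Interferon response genes were lower in males in 33 of 33 (median -0.91), with Isg15 at -1.81 ± 0.49 and Ifit1 at -1.72 ± 0.52. Lung markers were lower in 12 of 13 (median -7.70), with the surfactant protein gene Sftpd at -8.81 ± 2.90 and Cldn18 at -10.09 ± 3.29.

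Adjusted over the list alone, 18 fatty acid oxidation genes rose, 16 interferon genes fell, and 12 lung markers fell and 1 rose in WT males relative to WT females, against 0 over all genes for each. Camera adjusted p was 1.91e-15, 1.00e-11 and 6.71e-04, and with an estimated correlation adjusted p = 0.546 for each. Lung transcripts were highest in WT female replicate 2, and without the 4 thymus-rich libraries 0 lung markers fell adjusted over the list alone. WT male replicates 1 and 2 had the highest fatty acid oxidation levels of the WT libraries. Without the 4 low cell cycle libraries, which leaves WT male replicate 3 as the only WT male, 1 fatty acid oxidation gene rose (median 0.45) and 0 interferon genes fell (median -0.47), adjusted over the list alone. The test called 1 gene by edgeR, with 4051 at an unadjusted p under 0.05, against 694 by DESeq2 and 5681 by limma voom with sample quality weights. Leaving out WT male replicate 3 gave 585 edgeR calls, and leaving out WT male replicate 1 or 2 or WT female replicate 2 or 3 gave 0. In the fit with 585 calls, WT male replicates 1 and 2, both of low cell cycle level, were the only WT males.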

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

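The tests of thymus tissue, of circulating T cells, of the genotype, of reads from another library, of male reads and of endothelial and fibroblast content below were chosen after the patterns had been seen, while those of cartilage genes and of age were written down before their results.

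A library far from the other 5 of its genotype was found for 4 of 57 sets of 6 libraries (19 genes in 3 genotypes), where chance gives about 1 in 20, or 2.85 sets. Klrg2 was at 1.39 CPM in WT female replicate 3, against 0.568 to 0.852 in the other WT libraries. Xdh was at 37.8 CPM in het female replicate 1, against 6.53 to 9.76 in the other het libraries. Spock2 was at 65.9 CPM in that same library, against 39.4 to 46.5. Tnk2 was at 63.1 CPM in WT female replicate 2, against 34.3 to 41.2.

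The effect of the hom genotype differed between the sexes for 10 lists in the interaction test with camera's preset correlation, and that of the het genotype for 17. Median log2 differences (male minus female effect) of the hom interaction were -1.17 for fatty acid oxidation, 0.93 for glycolysis and hypoxia, 0.90 for the extracellular matrix, 1.63 for the cell cycle, 1.0 for the integrated stress response, 0.74 for the interferon response, -1.11 for the circadian clock, 1.07 for fibroblast markers, 1.19 for epicardial markers and 1.05 for Schwann and neuronal markers. Those of the het interaction were -0.33 for the sarcomere, -0.38 for ion channels, -0.24 for cardiac transcription factors, -0.30 for the respiratory chain, -1.47 for fatty acid oxidation, 0.58 for the extracellular matrix, 1.43 for the cell cycle, 0.66 for the integrated stress response, 0.48 for immediate early genes, 1.01 for the interferon response, -0.96 for the circadian clock, -0.32 for ventricular markers, 0.59 for fibroblast markers, 0.81 for erythroid markers, 1.32 for Schwann and neuronal markers, 5.68 for thymus markers and 6.30 for lung markers. None of the 27 calls held with an estimated correlation, where the smallest adjusted p was 0.679.

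Thymus transcripts in WT female replicate 2, hom male replicate 3 and hom female replicates 1 and 2 are consistent with thymus tissue in the dissected sample. Of 6 genes of thymic epithelium, which blood does not carry, 6 had these as their 4 highest libraries, with Prss16 at 130 CPM or more there and at most 14.3 CPM in the other 14. Prss16, Pax1 and Tbata were also among the genes at the upper end of the leading principal component, so they do not test the pattern independently. The same 6 genes argue against T cells of the circulating blood as the whole source. Whether genotype plays a part cannot be told apart from dissection with these libraries: the thymus level was 2.12 ± 4.30 in hom and -0.82 ± 3.55 in WT (SD, n = 6), and the exact two-sided permutation p was 0.212 where 0.00216 was the smallest possible. Surfactant and other lung transcripts were also high in WT female replicate 2 and hom female replicate 1.

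Minor thymus transcripts in WT, het and hom female replicate 3 may come from reads of another library. If a share of a source library set both thymus and lung transcripts, the thymus and lung ratios to that source would match; with the best matching of 4 sources taken for each library, the poorest match was a fold of 1.55, of hom female replicate 3 to hom male replicate 3, and other sources differed by up to 55.9. A test on summed lung CPM was added because that left the matter open, again with the best of 4 sources for each library: thymus shares of 8.57% from WT female replicate 2, 6.13% from hom female replicate 1 and 7.82% from hom female replicate 2 would bring 125, 64.3 and 4.73 CPM of lung transcripts, and 129, 60.7 and 4.39 were observed, within a fold of 1.08, while the other sources missed by 1.90 to 41.0. The choice of source favours a match, hom female replicate 2 has only 2 usable lung genes, and cartilage genes could not test this, with 1 usable gene where 3 were needed. The 4 Y-linked genes in het female replicate 1 had ratios to the male mean within a fold of 1.48, which is consistent with reads or cells of a male heart, and whether RNA, tissue or reads were mixed stays open.

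Low cell cycle and high fatty acid oxidation levels in WT male replicates 1 and 2, het female replicate 1 and hom female replicate 2 may reflect pups of a later age, since hearts turn from division to fatty acid use after birth. The fatty acid oxidation level went with a lower level of fetal growth genes over 18 libraries (Pearson r = -0.547, permutation p = 0.019, adjusted 0.028 over 3 relations; Spearman rho = -0.447, p = 0.064, adjusted 0.097), and r was -0.632 within groups. Without WT male replicate 2 and het female replicate 1 it was -0.365, so the relation rests in part on those libraries. Fewer endothelial cells would lower endothelial markers with the cell cycle level, and the slope was -0.0153 with an upper 95% bound of 0.121, which argues against that as the whole cause. Fewer fibroblasts stay open. The slope of the log2 summed fibroblast markers was 0.385 (95% interval 0.148 to 0.622) and that of their mean level 0.158 (-0.0117 to 0.328). Age was tested only through the fetal growth genes, as the labels give a single age. Feeding and time of death were not tested, and the low libraries are spread over 3 groups.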

How the results depend on the processing

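The fits without groups of libraries and with list levels as covariates were chosen after seeing the data; all others were planned. Of the counts of genes past the threshold in 10 comparisons, 176 alternative counts stayed at the main edgeR count or within 1.5 times of it, 44 were higher (9 comparisons) and 10 of the sex comparison were 0 where the main count was 1. Of single genes named, 10846 alternative values stayed on the same side of the threshold, some with another sign below it (Chd7 in hom against WT in 14 of 26), 452 newly passed and 10 no longer passed (Uty in the sex comparison). Of list tests 687 were the same, 302 no longer passed (6 with the replicate block, the others with an estimated correlation or fry) and 1 newly passed. None of these tests turned a gene or list past its threshold to the other direction, but medians of several lists turned when libraries were left out, as in the cell cycle of hom against WT. The cause was not tested where none is given.

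DESeq2 called 40 genes in hom against WT over both sexes, 1100 in hom against het, 1430 in hom males, 23 in hom females, 328 in het males, 737 in the hom interaction, 280 in the het interaction and 694 between the sexes in WT. Limma voom with sample quality weights called 1763, 2490, 4900, 4691, 7245, 6182, 3435 and 5681 in that order, and 1205 in het against WT over both sexes. Between the sexes in WT, 0 genes passed with no filter on low counts, with only the groups of the contrast, without the 4 thymus-rich or the 4 low cell cycle libraries, and with thymus, lung and fatty acid oxidation levels as covariates. With only the groups of the contrast 1 gene passed in hom males and 1 in het males. Surrogate variables gave 1 in hom males and 1 in hom against het. RLE size factors, the stricter filter, the test against a fold of 1.2 and covariates for thymus and lung left all 10 counts as they were.

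Without the 4 thymus-rich libraries, which leaves hom female replicate 3 as the only hom female, assumed to vary like the other groups, edgeR called 3 genes in hom against WT over both sexes, 2 in hom against het, 1 in hom males, 544 in hom females and 1532 in the hom interaction. Without 7 libraries, which also leaves WT male replicate 3 alone in its group, it called 242, 301, 35, 2256 and 1447 in the same order, 1 in het males, 1 in the het interaction and 4 between the sexes. Leaving out each library in turn gave 0 to 983 calls in hom against het, 0 to 1331 in hom males, 0 to 632 in het males, 0 to 1259 in the hom interaction, 0 to 359 in the het interaction and 0 to 585 between the sexes, and 0 in the other 4. The highest counts came without hom female replicate 3 in hom against het and without WT male replicate 3 in the others. Without hom female replicate 3, the only hom females are replicates 1 and 2, both rich in thymus transcripts. Without WT male replicate 3, the only WT males are replicates 1 and 2, both of low cell cycle level. Those counts may therefore reflect these libraries rather than genotype or sex.

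The replicate number as a block gave 0 calls in all 10 comparisons, so it moved only the sex comparison, from 1 to 0, and in the list tests 1 call was gained, glycolysis and hypoxia in het females (camera adjusted p = 0.0398). The numbers gave no sign of pairing the libraries. Deviations from the group means correlated at -0.0263 on average between same-numbered and 0.0119 between other libraries. Of 45 same-numbered pairs 16 lay above 0.1, and 3 of 18 libraries were closest to their own number. Differences in thymus content within groups are large, so a weaker pairing could stay hidden.

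Depth was not varied. At these library sizes and spreads, edgeR recovered 20% of simulated 1.5-fold changes in hom against WT over both sexes and 8% in males, so changes of this size are mostly missed. The simulation lacks the shared differences between libraries, so it does not show that larger changes would be found here. Between WT males and WT females, even Kdm5d, Eif2s3y, Ddx3y and Xist did not pass. In the hom females, with 14.1 megareads in the shallowest library, genes under 1 CPM rest on few reads.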

Other observations

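Of the tests below, that of genes near Chd7 and the splits of the libraries were set before their results were seen, and that of Uty after.

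Levels of heart muscle differentiation varied between libraries of a group. The ratio of the fetal to the adult myosin heavy chain, Myh7 to Myh6, was 0.182, 0.348 and 0.724 in WT males, 0.593, 0.560 and 0.832 in WT females, 1.09, 0.708 and 0.675 in het males, 0.109, 0.628 and 0.806 in het females, 0.758, 0.615 and 0.753 in hom males and 0.753, 0.172 and 0.258 in hom females. Across the 18 libraries the fatty acid oxidation and cell cycle levels moved in opposite directions (Pearson r = -0.866, permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted 3e-05 over 3 relations; Spearman rho = -0.779, p = 2.4e-04, adjusted 7.2e-04). The relation was -0.786 without the 2 libraries farthest from the median fatty acid oxidation level and -0.798 within groups. Cell cycle and endothelial levels were not related (r = -0.0594, p = 0.83; rho = -0.158, p = 0.53, both unchanged by adjustment).

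Uty was lower in males that carry the allele, at 19.2 ± 2.14 CPM in 6 het and hom males against 35.0 ± 3.49 CPM in 3 WT males (SD), a ratio of 0.547 with no overlap between the libraries. An exact two-sided permutation test gave p = 0.0119, the smallest this design allows, and 0.0476 adjusted over 4 Y-linked genes. The ratio was 0.996 for Ddx3y, 0.840 for Kdm5d and 0.795 for Eif2s3y (exact adjusted p = 0.988, 0.0794 and 0.0476). Fewer male reads would lower all 4 genes alike, while their ratios spread over a fold of 1.82. The edgeR tests of Uty in hom and in het against WT males gave adjusted p = 0.441 and 0.611. Of 20 alternative settings each, Uty passed in 1 (limma voom, adjusted p = 0.00749 and 5.09e-04), and its sign turned in 2, with surrogate variables (0.41 and 0.19) and with thymus, lung and fatty acid oxidation covariates (1.0 and 0.38). A Y chromosome of another origin in the mutant line was not tested.

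As a test of strain passenger genes linked to Chd7, of 70 tested genes within 10 Mb of Chd7, 10 had an unadjusted p under 0.05 in hom against WT, and 2552 of 19683 genes elsewhere did, an odds ratio of 1.12 (95% interval 0.510 to 2.21, Fisher's exact p = 0.721). The interval includes a doubling, so the test leaves passengers open.

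Other splits of the same libraries show how far the counts of edgeR calls speak for the labelled groups. For contrasts of 4 groups 30 splits were fitted, the labelled one included. With a real count of 0, all 30 give as many by construction, so these counts test nothing. The highest other count was 3132 for hom against WT, 0 for het against WT, 0 for hom against het, 1 for the hom interaction and 1 for the het interaction. At an unadjusted p under 0.05 the real and highest other counts were 2562 and 6426, 478 and 2988, 3807 and 4262, 3696 and 4151, and 2792 and 3647 in that order, while DESeq2 called 40, 0, 1100, 737 and 280 genes in the labelled groups and limma voom 1763, 1205, 2490, 6182 and 3435. As many as the real unadjusted count came from 7, 12, 2, 3 and 2 of the 30 splits, so chance cannot be excluded. A split that calls 3132 genes where the labelled groups give 0 points to a structure of the samples.

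Splits of 3 against 3 libraries number 10, too few for a share under 0.05. With edgeR the real and highest other counts were 0 and 0 in hom against WT males, 0 and 5006 in hom against WT females, 0 and 0 in het against WT males, 0 and 0 in het against WT females, and 1 and 13 between the sexes in WT. In the first 4 all 10 splits reach a real count of 0 by construction, and 2 of 10 gave as many as the real 1 between the sexes. At an unadjusted p under 0.05 the pairs were 4459 and 3006, 1592 and 7951, 2575 and 1306, 813 and 1622, and 4051 and 3156. With DESeq2 they were 1430 and 222, 23 and 5712, 328 and 40, 0 and 183, and 694 and 783 at its adjusted p, and limma voom called 4900, 4691, 7245, 0 and 5681 genes in the labelled groups. The splits of the hom and WT females that call 5006 and 5712 genes point to a structure of the samples. In males the labelled split holds WT male replicates 1 and 2, both of low cell cycle level, on the same side. Some of the other splits do so too, with counts no higher than the highest other counts given. With 10 splits and the WT males so grouped, the higher counts of the labelled split cannot tell genotype from that difference between libraries.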
